A study of Mus musculus with 16 samples.

How the data were processed

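Total RNA was taken with TRIzol from the livers of 16 male C57BL/6 mice, 4 in each of the control, alcohol, DADS and garlic oil groups, and 500 ng per mouse was made into biotin-labelled cRNA for 1-colour Illumina BeadChips, per the labels. The deposited intensity of each array is the mean bead signal of 25697 probes on a linear scale, not normalized and with background not subtracted (lowest value 47.9, medians from 95.9 to 116.7). A deposited p-value beside each signal, per the file headers, gives the detection of the probe over negative controls. The deposited table of all samples holds intensity on a linear scale, background-adjusted and normalized by the authors. The exact method is not given in the sources used here, and GenomeStudio, lumi and limma are named without versions per the submitters' processing notes. Each of its 16 columns ranked the probes exactly as the signal of its own array (Spearman correlation 1), its lowest value was 2.7464, and no column belonged to another sample. The identifiers of the array files place the 16 arrays on 2 chips of 8, with DADS and garlic oil on 1 chip and control and alcohol on the other. By the same identifiers, DADS and control arrays held positions 1 to 4 of their chips, and garlic oil and alcohol arrays positions 5 to 8. Within a chip, group and position therefore cannot be told apart.

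The scanner signals were background-corrected and quantile-normalized with limma's neqc (offset 16), which estimated the negative control level from the detection p-values, and were brought to the log2 scale. Probes with a detection p under 0.05 on at least 4 of 16 arrays were kept, which 11938 probes met. Arrays detected between 10631 and 11526 probes each, and replicates of a group correlated at between 0.973 and 0.993. By the deposited annotation, 23978 probes had 1 gene symbol, 0 had several and 1719 had none, and 708 probes without a name passed the filter. Of 11230 named probes that passed, the probe with the highest mean stood for its gene, which gave 8386 genes, 2104 of them with more than 1 passing probe. In no comparison against alcohol or between the treatments did a called gene have another called probe of opposite sign, nor in alcohol against control, and 3 and 4 such genes were found for DADS and garlic oil against control. Cyp2b, Gsta, Mup and globin genes have near-identical relatives, so probes of these families may not be specific to 1 member. No genome coordinates were used here.

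Comparisons were made in 1 limma fit of the 16 arrays with 4 group means (12 residual degrees of freedom) and moderated, two-sided t-tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 over 8386 genes counted as changed, as rising or as falling. The median SE of a log2 change was 0.162. A fold against a group whose arrays all missed detection is given as a lower bound, taken against the detection limit of those arrays or the value itself where higher. The same bound is given where only some arrays detected the gene and the group mean lay under the limit. Where only some arrays detected it and the mean lay above the limit, the plain fold is given. The size of such a fold is uncertain. Principal component 1 held 29.75% of the variance. Tested on simulated data with 200 changed genes in 20 runs of alcohol against control, the method recovered 29.9% of changes of 0.5 on the log2 scale, 85.7% of changes of 1 and 99.1% of changes of 2, with 4.83% of calls false. It made 0 gene calls and 0.05 list calls per run where nothing changed, and it called a list shifted by 0.3 in 20 of 20 runs. The simulated genes varied independently of each other, so these list rates do not hold for lists whose genes vary together. Each simulated gene also had 1 spread in all groups and no outlying array. The real spread within a group averaged 0.216 for control and 0.324 for alcohol arrays on the log2 scale. The gene rates may therefore not hold for these data.

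Before the data were examined, 37 gene lists of liver pathways, stress responses, sex-biased and zone-specific genes and cell type markers were fixed. Those with at least 4 measured genes were tested with limma's camera at a preset correlation of 0.01 (36 lists; an adipocyte list had too few), with p-values adjusted over lists, and alternatively with an estimated correlation and with fry. Numbers adjusted over a list alone used only the genes of that list. The genes named in each comparison were set by a rule: the 10 largest rises and 10 largest falls among changed genes detected on all 4 arrays of the higher group, leaving out provisional names, then up to 4 changed members of each list by smallest p, and 18 genes of alcohol, lipid, bile acid and stress biology whatever their values. Of these 18, Cd36 (detected on at most 2 arrays) and Tnf (detected on 0) were not tested, and 1 other is not reported here. A few genes outside the rule are named among those that changed with both treatments or moved back, and were chosen after their values were seen.

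The alternatives fixed in advance were no background correction, median scaling, cyclic loess, the authors' values, no filter, detection on all 16 arrays, all probes, array weights, a trended and robust variance, only the 2 groups compared, the arrays of a chip alone, replicate number as a block, each array left out in turn, and the alcohol arrays split 2 and 2. Removing alcohol replicate 1 before normalization was added after seeing the data. Because both treatments were compared with the same alcohol arrays, 100 simulations with permuted residuals gave the shares moved back and the correlation that this sharing produces with no treatment effect or chip difference. R 4.3.3, limma 3.58.1, jsonlite 2.0.0, Python 3.11.15 and matplotlib 3.10.9 were used.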

Results

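Liver RNA of 16 male C57BL/6 mice was measured on Illumina BeadChips, 1-colour arrays that read each transcript with bead-bound probes. The mice fell into 4 groups of 4, described by the labels as biological replicates. Control mice received a Lieber-DeCarli liquid diet without ethanol, pair-fed to the ethanol groups. Alcohol mice received the ethanol form of this diet, a model of alcoholic fatty liver. DADS mice received the ethanol diet and 15 mg/kg of diallyl disulfide, an organosulfur compound found in garlic, by daily gavage for 4 weeks. Garlic oil mice received the ethanol diet and 50 mg/kg of garlic oil, a mixture that contains allyl sulfides. The vehicle was 0.1 ml of olive oil in every group. Each array detected between 10631 and 11526 probes, and 8386 genes were bright enough to be tested. Replicates of a group correlated at between 0.973 and 0.993 over these genes, and the number of arrays limits the precision of each comparison. The control and alcohol arrays lay on 1 chip and the DADS and garlic oil arrays on another, with each group in its own block of positions. Changes are given as log2 values ± SE from limma's fit with n = 4 mice per group and Benjamini-Hochberg adjusted p-values, unless another error is named.

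Alcohol feeding was first set against the control diet, to ask how ethanol changed liver expression. Cyp2b10, a cytochrome P450 and a classical target of the receptor CAR, was detected on none of the control arrays and was at least 18.6-fold higher in alcohol mice (adjusted p = 5.29e-06). Gsta1, a glutathione S-transferase, rose 42.9-fold (5.42 ± 0.56, adjusted p = 2.34e-05). Cyp7a1, the rate-limiting enzyme of the classical bile acid pathway, fell 15.6-fold (-3.96 ± 0.68, adjusted p = 0.00352). In all, 300 genes changed, 163 upward and 137 downward, of which 57 rose and 35 fell at least 2-fold, and 1515 genes had an unadjusted p under 0.05.

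Among 23 measured targets of CAR and PXR, nuclear receptors that control drug metabolism, 9 rose and none fell (12 rose and 1 fell when adjusted over the list alone). Cyp2b13 was at least 14.3-fold and Cyp2b23 at least 5.3-fold higher, both undetected in controls. Cyp2b9 rose 30.3-fold (4.92 ± 0.33, adjusted p = 2.23e-07), with detection on 2 of 4 control arrays. Cyp2a5, a coumarin hydroxylase, rose 4.22-fold (adjusted p = 2.86e-05). The list had an adjusted p of 2.51e-12, and adjusted p = 0.0463 with an estimated correlation. Among 25 targets of NRF2, the regulator of antioxidant genes, and glutathione enzymes, 9 rose and none fell (13 and none adjusted over the list alone). Gsta2 rose 9.95-fold, Cbr3, a carbonyl reductase, rose 7.23-fold (2.85 ± 0.65, adjusted p = 0.0195), Gstm1 rose 4.02-fold (2.01 ± 0.20, adjusted p = 1.63e-05) and Gstm3 was at least 2.7-fold higher. Gsta1 was detected on 2 of 4 control arrays, Gstm3 on none. This list had an adjusted p of 2.57e-12, and adjusted p = 0.0921 with an estimated correlation. Other classical NRF2 targets did not pass: Nqo1 changed by 0.71 ± 0.29 (adjusted p = 0.197), Gclc by 0.39 ± 0.31 (adjusted p = 0.547) and Hmox1 by -0.14 ± 0.26 (adjusted p = 0.817). Of 5 targets of AHR, the dioxin receptor, only Cyp1a2 rose (0.65 ± 0.17), and the list had an adjusted p of 0.0138 (adjusted p = 0.254 with an estimated correlation).

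**Figure D1:**
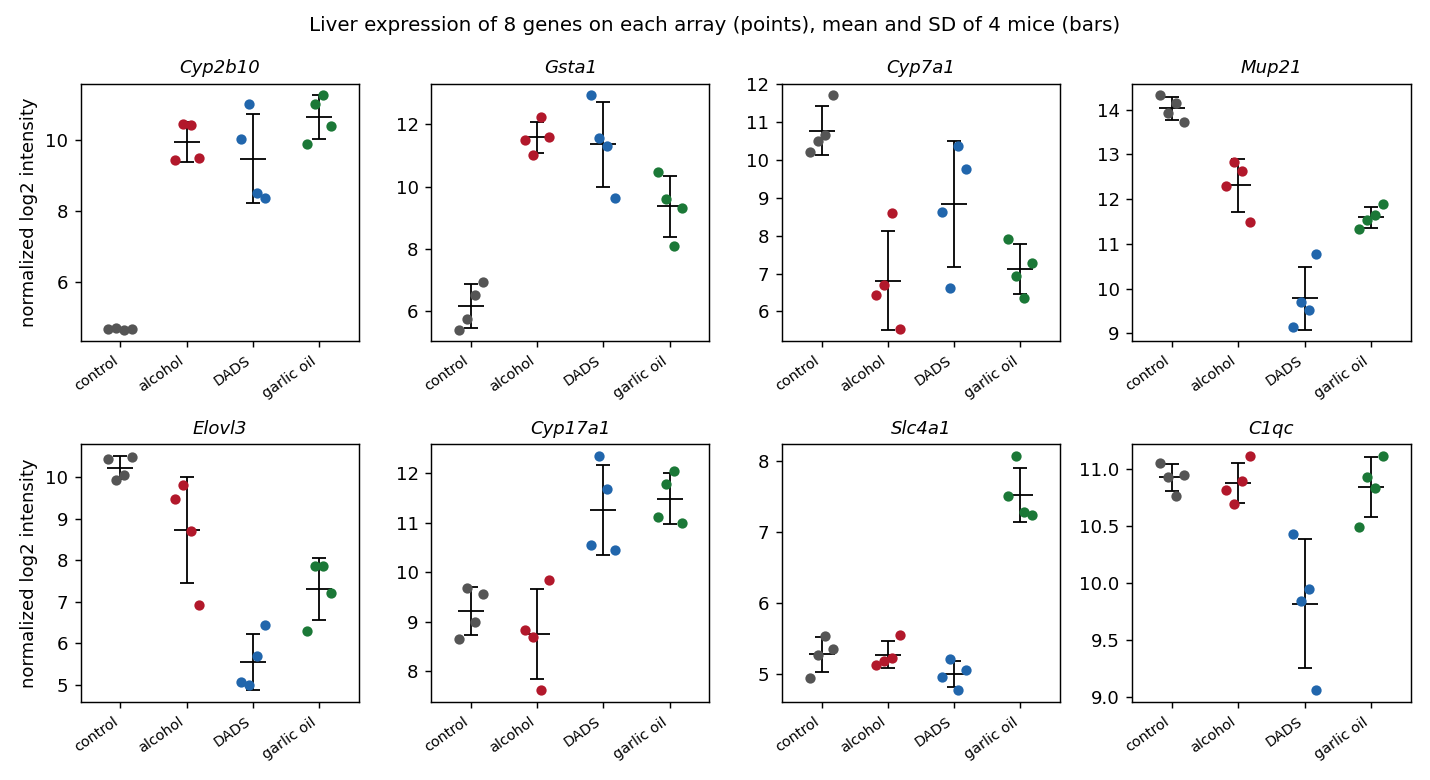
Normalized log2 intensity of 8 genes (vertical axis) on each of the 16 arrays, by group (horizontal axis); points are arrays, the long bar is the mean and the whiskers are the SD of 4 mice. Cyp2b10 lay near 4.69 on all control arrays and averaged 9.95 in alcohol mice, and Slc4a1 averaged 7.53 with garlic oil against 5.28 in alcohol mice.

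None of 11 measured genes of ethanol oxidation passed, and the list had an adjusted p of 0.886. The change of Cyp2e1, the ethanol-inducible P450, was -0.06 with a 95% interval from -0.26 to 0.15. Aldh2, the main acetaldehyde dehydrogenase, changed by -0.01 (-0.21 to 0.19) and Adh1 by 0.30 (-0.04 to 0.64). Retinoid genes moved both ways. Cyp26a1, which degrades retinoic acid, was at least 5.4-fold higher (adjusted p = 2.34e-05; detected on 2 of 4 control arrays) and Aldh1a7 rose by 0.63 ± 0.15, while the retinol dehydrogenases Rdh9 (-0.84 ± 0.20) and Dhrs4 (-0.80 ± 0.14) fell. As a list, 11 retinol genes had an adjusted p of 0.955.

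Of 4 lipid lists, those of fatty acid oxidation and cholesterol synthesis passed, both downward, and neither passed with an estimated correlation. Of 27 measured genes of fatty acid oxidation and other targets of the receptor PPARA, 3 fell and none rose (6 and none adjusted over the list alone), with an adjusted p of 4.04e-07 (adjusted p = 0.182 with an estimated correlation). They were Fgf21, a liver hormone (-1.97 ± 0.50, adjusted p = 0.0375), Crat, a carnitine acyltransferase (-1.01 ± 0.25), and Decr1 of unsaturated fatty acid oxidation (-0.78 ± 0.18). G0s2, an inhibitor of triglyceride lipolysis, fell 5.29-fold (-2.40 ± 0.28, adjusted p = 5.69e-05). The lipid droplet protein Plin4 rose 2.86-fold and Lpin1, a phosphatidate phosphatase, rose 5.9-fold (2.56 ± 0.42, adjusted p = 0.00221). Fabp1, a fatty acid-binding protein, fell 1.74-fold. The polyunsaturated fatty acid enzymes Fads2 (-0.76 ± 0.15) and Elovl5 (-0.72 ± 0.13) fell. No member of the cholesterol synthesis list passed in this fit, although 14 of 18 were lower and the list had an adjusted p of 0.00407 (adjusted p = 0.599 with an estimated correlation). With the control and alcohol arrays normalized and fitted alone, 4 members fell and 0 rose. The list then had an adjusted p of 3.23e-06 (adjusted p = 0.184 with an estimated correlation). Lipogenesis (22 genes, adjusted p = 0.74) and lipid uptake, droplets and export (16 genes, adjusted p = 0.365) did not pass as lists. Neither did Srebf1 (0.21 ± 0.28), Scd1 (0.64 ± 0.31), Fasn (0.22 ± 0.18), Plin2 (0.18 ± 0.32), Cpt1a (-0.12 ± 0.17) or Cyp4a14 (-0.55 ± 0.22) as single genes.

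Genes that differ between the livers of male and female mice moved as well. All 16 measured male-biased genes were lower, and 4 of them fell (6 adjusted over the list alone): C6, a complement component (-1.32 ± 0.29), Cyp7b1, an oxysterol hydroxylase (-1.18 ± 0.31), Susd4 (-1.10 ± 0.28) and Cyp2u1 (-0.96 ± 0.18). The list had an adjusted p of 6.35e-07 (adjusted p = 0.255 with an estimated correlation). Alcohol replicate 4 lay lower on this list than the other alcohol arrays, whose medians were also below the control mean. Mup21, a major urinary protein, fell 3.29-fold (-1.72 ± 0.30, adjusted p = 0.00392), and Socs2, a growth hormone-induced inhibitor of cytokine signalling, fell 6.01-fold. Of 6 female-biased genes 2 rose, both of them the Cyp2b9 and Cyp2b13 counted above (list adjusted p = 0.00195, and adjusted p = 0.182 with an estimated correlation). Other large falls were Tsc22d1, a transcriptional regulator (7.99-fold), Irs2, an insulin receptor substrate (4.36-fold), Nrep (4.01-fold) and Lamb3, a laminin chain (3.19-fold). Irs2 was detected on 2 of 4 alcohol arrays.

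Some metabolic zone markers rose on both sides of the liver lobule. Of 14 pericentral hepatocyte genes 5 rose (7 rose and 2 fell adjusted over the list alone), among them Rhbg, an ammonia transporter (1.49 ± 0.21), Glul, glutamine synthetase (0.87 ± 0.19), and Slc1a2, a glutamate transporter (0.68 ± 0.13). Of 12 periportal genes 3 rose (4 adjusted over the list alone), namely Etnppl (1.28 ± 0.26), Ass1 of the urea cycle (0.83 ± 0.17) and Hal, which degrades histidine (0.62 ± 0.15). Adjusted p was 6.96e-05 for pericentral and 0.000158 for periportal genes, and adjusted p = 0.0971 and adjusted p = 0.114 with an estimated correlation. The amino acid catabolism list shares Ass1 and Hal and also held Prodh (0.96 ± 0.18), giving 3 of 19 risen (adjusted p = 0.0231, adjusted p = 0.496 with an estimated correlation, and adjusted p = 0.107 under median scaling).

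Stress and cycle genes changed in part. Of 13 cell cycle genes 3 rose: Cdkn1a, an inhibitor of the cycle (6.99-fold, adjusted p = 0.00677), Cdc20, an activator of mitotic exit (at least 1.58-fold), and Mcm6 of DNA replication (0.91 ± 0.20). That list had an adjusted p of 0.000855 (adjusted p = 0.0921 with an estimated correlation). Cdkn1a was detected on 2 of 4 control arrays. Ddit4, an inhibitor of mTORC1, rose 6-fold (2.59 ± 0.50, adjusted p = 0.00834). Of 24 acute phase genes 3 rose (7 adjusted over the list alone), namely the metallothioneins Mt1 (2.54-fold) and Mt2 (3.94-fold), which bind metals, and Saa4, a constitutive serum amyloid (0.89 ± 0.22). The acute phase list had an adjusted p of 0.000249 (adjusted p = 0.255 with an estimated correlation). Mt2 was detected on 2 of 4 control arrays. Of 24 proteasome genes 23 were higher and 2 rose, Psmd14 (0.51 ± 0.13) and Psmd11 (0.46 ± 0.12), with an adjusted p of 1.19e-06 (adjusted p = 0.137 with an estimated correlation). Chac1, which degrades glutathione, rose 2.93-fold and Atf4, its upstream transcription factor, fell (-0.59 ± 0.14), while the list of ER stress genes did not pass (adjusted p = 0.472). Of 13 clock genes 3 fell, Dbp 3.74-fold (-1.90 ± 0.39), Nr1d1 2.53-fold (-1.34 ± 0.28) and Tef 1.65-fold, and the list did not pass (adjusted p = 0.163). Immediate early genes were lower as a list (adjusted p = 0.0337, and adjusted p = 0.504 with an estimated correlation), with no single member past the test.

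Of 23 interferon response genes 20 were lower and 2 fell (7 adjusted over the list alone), Irf9, a subunit of the interferon-activated factor (-0.68 ± 0.12, adjusted p = 0.00392), and Rsad2 (-1.07 ± 0.24), with an adjusted p of 0.000158 (adjusted p = 0.182 with an estimated correlation). Of 17 stellate cell and fibrosis markers the collagens Col3a1 (1.13 ± 0.27) and Col6a1 (0.78 ± 0.20) rose and Reln fell (-0.59 ± 0.15), with a list adjusted p of 0.0116 (adjusted p = 0.351 with an estimated correlation). Pancreatic acinar genes stood apart on 1 array: their median on alcohol replicate 1 lay 9.64 log2 units above the control mean. Without that array the stellate list was still higher, with a median change of 0.232 and an adjusted p of 0.0529. This loss of the call alone does not tie the list to that array. No marker of Kupffer cells, neutrophils, lymphocytes, endothelium, cholangiocytes or red cells passed, with list adjusted p-values of 0.226, 0.34, 0.372, 0.237, 0.151 and 0.34. The acinar list itself had an adjusted p of 0.0883. Vcam1, an adhesion molecule, was the single inflammatory gene to rise (list adjusted p = 0.819). Bile acid genes (2 of 20 fell, Cyp7a1 and Cyp7b1), heat shock genes, glucose metabolism genes, one-carbon genes, oxidative phosphorylation genes and hepatocyte secreted proteins had list adjusted p-values of 0.34, 0.237, 0.283, 0.655, 0.499 and 0.499. The median, the mean and the test of a list differed in sign for retinol, lipogenesis, lipid droplet, ER stress, inflammatory and one-carbon genes, none of which passed as a list.

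Control and alcohol arrays shared a chip, where group cannot be told apart from position. Of the 63 named calls 32 held under every alternative and 8 were lost under most of them, among them Cyp1a2, Cyp7b1, Mt2, Psmd14, Psmd11, Susd4 and Col6a1. Normalized and fitted alone, those 8 arrays gave 306 changed genes, 56 of the 63 named calls and 16 lists, the same number as in the fit of all arrays, but no list passed there with an estimated correlation. The count was 132 without alcohol replicate 3, 137 without control replicate 1, 143 without control replicate 2, 196 without control replicate 3 and 669 with array weights. Without the acinar-rich array it was 223, and Socs2, Fgf21, Cyp1a2, Mt2, Saa4, Aldh1a7, Cyp7b1, Susd4, Rsad2, Vcam1, Hal, Psmd14, Tef, Fabp1 and Col6a1 no longer passed, at adjusted p between 0.05 and 0.096. All 15 kept their sign in that fit, which has 1 array fewer.

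DADS was then compared with alcohol alone, to ask how the compound changed liver expression on the ethanol diet. Of 16 male-biased liver genes 7 fell and of 6 female-biased ones 4 rose, although neither list passed with an estimated correlation (adjusted p = 0.18 and adjusted p = 0.0764). Elovl3, a fatty acid elongase of male liver, was at least 7.52-fold lower (adjusted p = 0.00397; detected on 2 of 4 DADS arrays), Mup21 fell 5.75-fold (-2.52 ± 0.30, adjusted p = 0.00114) and Cyp17a1, a steroid hydroxylase, rose 5.69-fold (2.51 ± 0.44, adjusted p = 0.0071). Of 13 macrophage markers 7 fell, a list that did not pass with an estimated correlation either (adjusted p = 0.18). In all, 238 genes changed, 103 upward and 135 downward (23 and 41 at least 2-fold), and 1541 had an unadjusted p under 0.05.

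All 16 male-biased genes were lower with DADS and 7 fell (12 adjusted over the list alone), with a median change of -1.05 and an adjusted p of 1.14e-12 (adjusted p = 0.18 with an estimated correlation). Beside Elovl3 these included C6 (3.45-fold), Mup20 (-1.05 ± 0.18), Cyp4a12a, a male-specific fatty acid hydroxylase (6.13-fold), Serpina1e, an α1-antitrypsin family member (8.8-fold, adjusted p = 0.0381), and Cyp2u1, which was detected on no DADS array. All 6 female-biased genes were higher and 4 rose (5 adjusted over the list alone), with an adjusted p of 6.4e-08 (adjusted p = 0.0764 with an estimated correlation). They were Cyp17a1, Cyp2b9 (3.75-fold), Cyp2c39 (at least 1.61-fold, detected on 1 of 4 alcohol arrays) and Cux2, a female-specific liver transcription factor, which was at least 5.25-fold higher and detected on no alcohol array.

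Of the 23 CAR and PXR genes 4 rose (14 rose and 1 fell adjusted over the list alone), with an adjusted p of 8.15e-07 (adjusted p = 0.18 with an estimated correlation): Cyp2b9, Cyp2c39, Cyp2b23 (3.03-fold) and Nr1i3, the gene of CAR (0.78 ± 0.18). Cyp2b10 did not pass (-0.47 ± 0.45, adjusted p = 0.624). NRF2 and glutathione genes had no member past the test (list adjusted p = 0.723). Of 27 fatty acid oxidation genes 3 rose (7 adjusted over the list alone), Acot3, a peroxisomal acyl-CoA thioesterase (7.34-fold, adjusted p = 0.0187), Cyp4a14 (1.95-fold) and Ppara (0.82 ± 0.16, adjusted p = 0.0123), with an adjusted p of 4.12e-05 (adjusted p = 0.413 with an estimated correlation). Apoa4, an apolipoprotein, rose 3.62-fold (1.86 ± 0.27, adjusted p = 0.003) and Vldlr, a lipoprotein receptor, 2.85-fold. Lpin1 fell 3.69-fold and G6pc, the catalytic unit of glucose-6-phosphatase, fell 2.94-fold (-1.56 ± 0.21, adjusted p = 0.00164). Car3, a carbonic anhydrase, fell 6.33-fold (-2.66 ± 0.34, adjusted p = 0.00114). Socs2 rose 4.65-fold, Gadd45a, a DNA damage-inducible gene, 2.98-fold, and Chil3, a chitinase-like protein, at least 1.94-fold (detected on 1 of 4 alcohol arrays). Tsc22d1, detected on 2 of 4 DADS arrays, fell 3.95-fold and the pseudogene Serpina4-ps1 3.86-fold.

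Of 13 Kupffer cell and macrophage markers 12 were lower and 7 fell (9 adjusted over the list alone), with a median change of -0.68 and an adjusted p of 6.4e-08 (adjusted p = 0.18 with an estimated correlation). They included the complement genes C1qa (-0.67 ± 0.15), C1qb (-1.15 ± 0.27) and C1qc (-1.06 ± 0.21), and Adgre1, which encodes F4/80 (-1.06 ± 0.25). Without the acinar-rich array of alcohol replicate 1 only 1 of the 13 passed, with a median change of -0.64 and a list adjusted p of 3.51e-07. The 4 DADS arrays had marker medians of 0.015, -0.588, -0.694 and -0.929 relative to the control mean, the first on DADS replicate 1. Of 7 lymphocyte markers 2 fell (5 adjusted over the list alone), Cd74, the invariant chain of antigen presentation (3.26-fold, adjusted p = 0.00623), and Cd79b of B cells (at least 1.69-fold, detected on 2 of 4 DADS arrays), with an adjusted p of 0.000166 (adjusted p = 0.338 with an estimated correlation). Alcohol replicate 1, the acinar-rich array, also had the highest lymphocyte median, 0.964 above the control mean. Inflammatory genes (adjusted p = 0.034, and adjusted p = 0.48 with an estimated correlation) and stellate genes (1 of 17 fell, Mmp2, a matrix protease, at -0.74 ± 0.16; list adjusted p = 0.0313, and adjusted p = 0.48 with an estimated correlation) were lower as lists, while the stellate median turned to 0.007 under median scaling. Without the acinar-rich array, with 1 array fewer, these lists had medians of -0.217 and -0.095 and adjusted p = 0.0524 and 0.13. The lost calls alone do not tie the lists to that array. The acinar list was lower by test (adjusted p = 0.0328, and adjusted p = 0.587 with an estimated correlation), and without that array its adjusted p was 0.801. Of 15 endothelial markers Lyve1 fell (-1.16 ± 0.28; list adjusted p = 0.0772).

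Of 6 erythroid genes Alas2, the red cell enzyme that starts heme synthesis, fell 2.87-fold (list adjusted p = 0.0179, and adjusted p = 0.338 with an estimated correlation). Cell cycle genes fell in part, with Mcm5 (-0.78 ± 0.19) and Cdc20 (at least 1.58-fold, detected on 1 of 4 DADS arrays) 2 of 13 (list adjusted p = 0.0179, and adjusted p = 0.183 with an estimated correlation), and 1 of 23 interferon genes, Bst2, fell (-0.87 ± 0.18; list adjusted p = 0.0328, and adjusted p = 0.48 with an estimated correlation). Tef rose 1.9-fold among 13 clock genes (list adjusted p = 0.0427, and adjusted p = 0.48 with an estimated correlation), a list call absent under median scaling (adjusted p = 0.136) and without the acinar-rich array (adjusted p = 0.0919). Proteasome genes were higher as a list (adjusted p = 0.0164, and adjusted p = 0.48 with an estimated correlation) with no single gene past the test. Other single calls outside the passing lists were Rdh9 (1.94-fold up), Akr1d1 of bile acid synthesis (at least 1.37-fold up, detected on 2 of 4 alcohol arrays), Apcs, an acute phase pentraxin (2.54-fold up), and Itih2 (1.43-fold up). The pericentral genes Tbx3 (1.8-fold up) and Axin2, a Wnt target (1.73-fold up), and the periportal P450 Cyp2f2 (1.65-fold down) were also called. Fabp1 fell by -0.759 on the log2 scale, further along its fall with alcohol (-0.796). Its call was kept under 12 of 18 alternatives. Fgf21 (1.89 ± 0.50, adjusted p = 0.0503) and Cyp7a1 (2.03 ± 0.68, adjusted p = 0.115) did not pass. Median, mean and test differed in sign for retinol, AHR, glucose, amino acid catabolism, oxidative phosphorylation, neutrophil and cholangiocyte genes, none of which passed as a list.

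DADS and alcohol arrays lay on different chips, so chip and group cannot be told apart in this comparison. Of 47 named calls 15 held under every alternative, while Socs2, Cyp2b23, Serpina1e, Akr1d1, Apcs, Axin2, Tbx3 and Cd79b were lost under most. The count was 98 without alcohol replicate 3, 110 without DADS replicate 3, 124 without alcohol replicate 2, 150 without alcohol replicate 1, 136 with no filter on dim probes, 63 with the arrays of these 2 groups alone, and 775 (676 upward, 99 downward) under median scaling, where the median change of all genes was 0.18 against 0.02 in the reported fit. Removing the acinar-rich array before normalization gave 151 and ended the calls of Socs2, Cyp2b23, Gadd45a, Vldlr, Serpina1e, Akr1d1, Apcs, Mcm5, Itih2, C1qa, C1qb, Adgre1 and Cd79b, at adjusted p between 0.0547 and 0.112. All 13 kept their sign in that fit, which has 1 array fewer, with C1qa at -0.638, C1qb at -1.097, Adgre1 at -1.075 and Socs2 at 1.864.

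**Figure D2:**
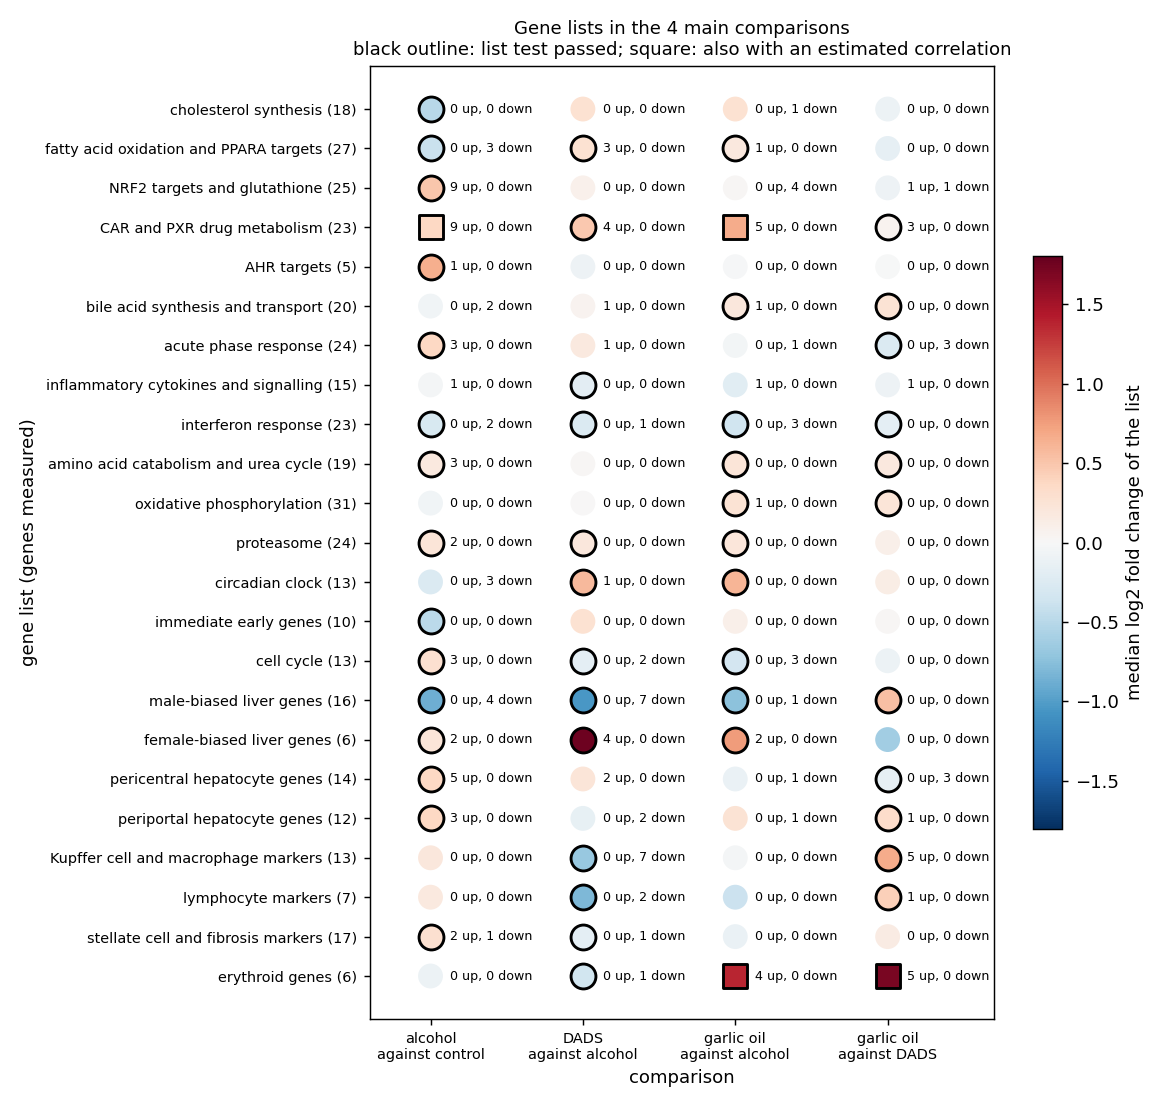
Gene lists (vertical axis, measured genes in brackets) in the 4 main comparisons (horizontal axis); colour is the median log2 change of a list, a black outline marks a list that passed its test, a square marks one that passed also with an estimated correlation, and the text counts genes that rose and fell. Male-biased genes had 4 and 7 falls in the first pair of comparisons, and erythroid genes had 4 and 5 rises in the last pair.

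Garlic oil was compared with alcohol in the same way. Of 6 red cell genes 4 rose, and of 23 drug-metabolism genes 5 rose. Slc4a1, the anion exchanger of red cells, was at least 3.65-fold higher (adjusted p = 2.59e-06; detected on 1 of 4 alcohol arrays) and Cyp17a1 rose 6.69-fold (2.74 ± 0.44, adjusted p = 0.00643), while Clstn3 fell 2.43-fold (-1.28 ± 0.18, adjusted p = 0.00148). In all, 169 genes changed, 58 upward and 111 downward (12 and 13 at least 2-fold), and 1550 had an unadjusted p under 0.05.

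Of 6 erythroid genes 4 rose, the same number when adjusted over the list alone: Slc4a1, the beta globins Hbb-b2 (3.5-fold) and Hbb-bt (2.99-fold) and the alpha globin Hba-a1 (2.25-fold, adjusted p = 0.00104). The list had an adjusted p of 1.46e-09, and adjusted p = 0.0167 with an estimated correlation. Alas2 did not move with them (-0.12 ± 0.24, adjusted p = 0.84). Hbb-b2 was detected on 2 of 4 alcohol arrays. All 23 CAR and PXR genes were higher and 5 rose (15 adjusted over the list alone), with a median change of 0.67 and an adjusted p of 1.93e-13, and adjusted p = 0.0167 with an estimated correlation. Slco1a4, an organic anion transporter, rose 3.5-fold (1.81 ± 0.23, adjusted p = 0.00104), Cyp2b9 2.68-fold, Papss2, a sulfate donor synthetase, 1.62-fold and Abcc3, an export pump, 1.53-fold. Cyp2b10 did not pass (0.69 ± 0.45, adjusted p = 0.43). Of 25 NRF2 and glutathione genes 4 fell (5 adjusted over the list alone): Gsta1 (4.64-fold, adjusted p = 0.0498, a call kept under 3 of 18 alternatives), Gstm3 (2.29-fold), Gstm1 (1.76-fold) and Gstp1 (1.69-fold). That list did not pass (adjusted p = 0.883), and its median (0.019) and mean (-0.129) differed in sign.

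Of 23 interferon genes 21 were lower and 3 fell (8 adjusted over the list alone), Oasl1 (2.22-fold, adjusted p = 0.0152), Bst2 (1.67-fold) and Irf7, a transcription factor of the response (1.6-fold), with an adjusted p of 1.57e-05 (adjusted p = 0.137 with an estimated correlation). Of 13 cell cycle genes 3 fell, the mitotic genes Cdc20 (at least 1.72-fold, detected on 1 of 4 garlic oil arrays) and Plk1, which no garlic oil array detected, and Mcm4 (1.74-fold), with an adjusted p of 0.0063 (adjusted p = 0.12 with an estimated correlation). Prc1, a protein of cell division, was at least 2.38-fold lower (adjusted p = 0.00864), and the histone genes H1f2 (2.49-fold) and H2ac7 (2.39-fold) fell. Male-biased genes were lower in 15 of 16 cases with 1 call, C6 (-1.19 ± 0.29; list adjusted p = 2.21e-05, and adjusted p = 0.449 with an estimated correlation). Cyp17a1 and Cyp2b9 were the 2 risen genes among 6 female-biased ones (list adjusted p = 0.000117, and adjusted p = 0.12 with an estimated correlation). Of 20 bile acid genes Akr1d1 was at least 1.84-fold higher, with detection on 2 of 4 alcohol arrays (list adjusted p = 0.00517, and adjusted p = 0.0622 with an estimated correlation), and Cyp7a1 did not pass (0.30 ± 0.68, adjusted p = 0.854).

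Of 31 oxidative phosphorylation genes 25 were higher and Ndufb9 of complex I rose (0.57 ± 0.14), with an adjusted p of 1.57e-05 (adjusted p = 0.148 with an estimated correlation). Ppara rose 1.56-fold among fatty acid oxidation genes, a call kept under 4 of 19 alternatives (list adjusted p = 0.00436, and adjusted p = 0.635 with an estimated correlation). Proteasome (adjusted p = 8.04e-06, and adjusted p = 0.148 with an estimated correlation), clock (adjusted p = 0.00298, and adjusted p = 0.148 with an estimated correlation) and amino acid catabolism genes (adjusted p = 0.01, and adjusted p = 0.511 with an estimated correlation) were higher as lists with no single call, and amino acid catabolism had an adjusted p of 0.0889 without the acinar-rich array. Other genes that rose were Fkbp5, a glucocorticoid-induced chaperone (2.61-fold, adjusted p = 0.00674), Hamp2 of the hepcidin family (2.71-fold), Vcam1 (1.81-fold), Fads2 (1.73-fold), Hspe1, a mitochondrial chaperonin (1.65-fold), and Ppargc1a, a coactivator of mitochondrial genes (at least 1.21-fold). Serpina4-ps1 (4.27-fold), the serum amyloid Saa3 (2.97-fold), Cyp26a1 (2.22-fold), G6pc (1.86-fold) and Sc5d of cholesterol synthesis (1.65-fold) fell. As for the NRF2 genes, median, mean and test differed in sign for retinol, lipogenesis, AHR, ER stress, macrophage, endothelial and cholangiocyte genes, none of which passed as a list.

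Garlic oil and alcohol arrays also lay on different chips, so chip and group cannot be told apart here either. Of 38 named calls 10 held under every alternative and 15 were lost under most: Hamp2, Cyp2b9, Gsta1, Saa3, C6, Cyp26a1, Sc5d, Ppara, Gstm1, Gstp1, Hspe1, Vcam1, Irf7, Bst2 and Ndufb9. The count was 44 without garlic oil replicate 4, 54 without alcohol replicate 2, 77 without alcohol replicate 3, 94 without garlic oil replicate 2, 95 without alcohol replicate 1, 109 without garlic oil replicate 3, 96 with array weights, 83 on the authors' values and 27 with these 2 groups alone. The balance of 58 genes up and 111 down was 105 and 38 under median scaling and 67 and 77 under cyclic loess, and removing the acinar-rich array before normalization ended the calls of Gsta1, Gstp1, Cyp2b9, Abcc3, C6, Bst2, Hamp2, Saa3, H1f2, Cyp26a1, Sc5d, Vcam1 and Ndufb9, at adjusted p between 0.0518 and 0.0946. All 13 kept their sign in that fit, which has 1 array fewer, with Gsta1 at -2.239, Cyp2b9 at 1.347, Vcam1 at 0.884 and Cyp26a1 at -0.947.

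The 2 treatments were compared directly, on arrays of 1 chip, although their doses differed: 50 mg/kg of the oil mixture and 15 mg/kg of the single compound. Treatment and position on that chip cannot be told apart. Lpin1 differed most, higher with garlic oil by 3.39 ± 0.42 on the log2 scale (adjusted p = 0.000364). Red cell genes were higher with garlic oil, with Slc4a1 at least 3.76-fold and Hbb-bt 4.63-fold (2.21 ± 0.20, adjusted p = 1.03e-05), and so were 5 of 13 macrophage markers, among them Marco, a scavenger receptor (3.11-fold, adjusted p = 0.0115), although that list did not pass with an estimated correlation (adjusted p = 0.145). Apoa4 was 2.68-fold lower with garlic oil (adjusted p = 0.0153) and Tbx3 2.5-fold lower (adjusted p = 0.00557). In all, 155 genes differed, 62 higher and 93 lower with garlic oil (34 and 20 at least 2-fold), and 1408 had an unadjusted p under 0.05.

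All 6 erythroid genes were higher with garlic oil and 5 passed, also when adjusted over the list alone, with a median difference of 1.72 and an adjusted p of 1.42e-15, and adjusted p = 0.00209 with an estimated correlation. On the arrays of this chip alone 4 passed, and the list kept an adjusted p of 6.83e-14 (adjusted p = 0.0155 with an estimated correlation). Of 13 macrophage markers 12 were higher and 5 passed (10 adjusted over the list alone), among them Marco, C1qb (2.19-fold), C1qc (2.03-fold) and Cd163 (1.63-fold), with a median difference of 0.67 and an adjusted p of 2.32e-09 (adjusted p = 0.145 with an estimated correlation). On this chip alone no single marker passed and the list had an adjusted p of 4.52e-08 (adjusted p = 0.404 with an estimated correlation). Cd74 was the 1 of 7 lymphocyte markers to pass (2.28-fold higher; list adjusted p = 0.0122, and adjusted p = 0.497 with an estimated correlation), and Vcam1 was 2.93-fold higher (adjusted p = 0.000845).

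Male-biased genes were higher with garlic oil in 13 of 16 cases (adjusted p = 0.000691, and adjusted p = 0.497 with an estimated correlation) with no single call on the list, while Mup21 was 3.5-fold (adjusted p = 0.00593) and Car3 3.78-fold higher. Of 14 pericentral genes 3 were lower, Tbx3, Axin2 (1.89-fold) and Gstm3 (2.39-fold), with a list adjusted p of 0.0154 (adjusted p = 0.439 with an estimated correlation, and adjusted p = 0.134 under median scaling). Of 12 periportal genes Cyp2f2 was higher (0.57 ± 0.14), with a list adjusted p of 0.000963 (adjusted p = 0.169 with an estimated correlation). Of 24 acute phase genes Itih3 (1.64-fold), Itih4 (1.55-fold) and Apcs (2.54-fold) were lower, with a list adjusted p of 0.00648 (adjusted p = 0.497 with an estimated correlation, and adjusted p = 0.122 under median scaling). Oxidative phosphorylation genes were higher in 30 of 31 cases (adjusted p = 4.67e-07, and adjusted p = 0.158 with an estimated correlation). Bile acid (adjusted p = 0.0154) and amino acid catabolism genes (adjusted p = 0.0122) were higher and interferon genes lower (adjusted p = 0.0457, and 0.0565 without background correction) as lists with no single call, and adjusted p = 0.145, 0.497 and 0.497 with an estimated correlation.

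Of 23 CAR and PXR genes 3 were higher with garlic oil, Slco1a4 (2.54-fold, adjusted p = 0.00771), Cyp3a11, the main PXR-induced P450 (2.48-fold), and Papss2 (1.57-fold). The list had an adjusted p of 0.0457 (adjusted p = 0.497 with an estimated correlation, and adjusted p = 0.0573 on this chip alone). Cyp2b10 did not pass, and its difference of 1.16 had a 95% interval from 0.21 to 2.11. The antioxidant gene Hmox1, heme oxygenase, was 2.06-fold higher (1.04 ± 0.26, adjusted p = 0.0445). Genes over 3-fold lower with garlic oil included Psat1 of serine synthesis (at least 3.1-fold, detected on 1 of 4 garlic oil arrays), the lipid droplet gene Cidec (3.79-fold), Gnat1 (3.44-fold), Extl1 (3.35-fold), Ifi27l2b (3.29-fold) and Nrep (3.23-fold). Smaller falls were Chil3 (at least 2.06-fold, detected on 1 of 4 garlic oil arrays), Tgm1, a transglutaminase (2.86-fold), Ly6d (2.83-fold) and Gadd45a (2.71-fold). Gnat1, Extl1, Ifi27l2b and Ly6d were each detected on 2 of 4 garlic oil arrays. Genes higher with garlic oil also included Upp2, a uridine phosphorylase (4.32-fold), Hbb-b2 (3.59-fold), Phf11d (3.38-fold), Ces3b, a carboxylesterase (3.23-fold), Hba-a1 (3-fold) and Ppargc1a (at least 1.25-fold). No difference between the compounds was found for Cyp2e1 (-0.01, 95% interval -0.22 to 0.19), Adh1 (-0.11, -0.45 to 0.23), Aldh2 (-0.03, -0.24 to 0.17), Scd1 (0.01, -0.64 to 0.66), Plin2 (-0.30, -0.98 to 0.37), Nqo1 (-0.23, -0.84 to 0.39) or Gclc (0.38, -0.27 to 1.03). The intervals, which carry no adjustment for the number of genes, excluded 0 for Cyp7a1 (-1.73, -3.16 to -0.29, adjusted p = 0.207) and Fgf21 (-1.70, -2.75 to -0.65, adjusted p = 0.0884), and neither gene passed. Median, mean and test differed in sign for retinol, cholesterol synthesis, AHR, inflammatory and hepatocyte secreted genes, none of which passed as a list.

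Normalized and fitted on its own chip, the comparison gave 39 genes, and 16 of the 39 named calls held within the chip, among them Lpin1 (adjusted p = 0.0016), Mup21, Tbx3, Apoa4, Slco1a4 and Vcam1, while those of Car3, Marco, Cidec, Psat1 and Hmox1 did not. Under all alternatives together 16 of the 39 held throughout, and Nrep, Gadd45a, Hmox1, Cyp3a11, Apcs, Cd163, C1qb and Cd74 were lost under most. The count was 72 without garlic oil replicate 4, 88 without garlic oil replicate 3, 97 without DADS replicate 3, 101 without garlic oil replicate 2, and 237 (46 higher, 191 lower) under median scaling.

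**Figure D3:**
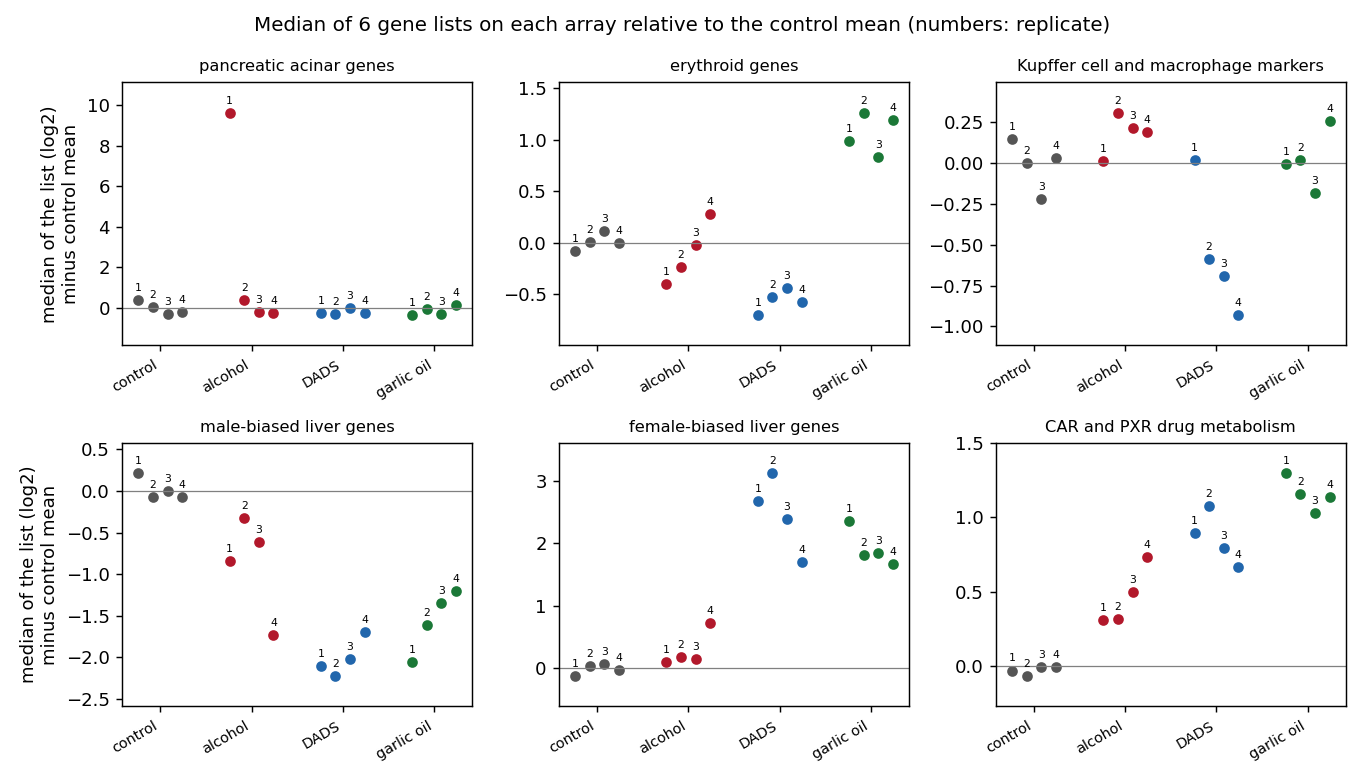
Median log2 value of 6 gene lists on each of the 16 arrays minus the mean of the control arrays (vertical axis), by group (horizontal axis), with replicate numbers beside the points. Acinar genes stood at 9.64 on alcohol replicate 1 alone, erythroid genes lay between 0.835 and 1.262 on the garlic oil arrays, and macrophage markers lay at or below -0.588 on 3 of 4 DADS arrays.

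Both treated groups were also set against control mice, to ask how far expression stayed from that of the control diet. DADS mice differed from controls in 1335 genes (711 higher, 624 lower) and garlic oil mice in 1497 (718 higher, 779 lower), with 2597 and 2727 genes at an unadjusted p under 0.05. Cyp2b10 averaged 9.48 ± 1.26 with DADS and 10.64 ± 0.62 with garlic oil (SD, n = 4) and was not detected in controls. Gsta1 remained above control in both, by 5.20 with DADS (adjusted p = 1.7e-05) and 3.21 with garlic oil (adjusted p = 0.00114). Tsc22d1 was lower in both, by -4.98 and -4.04, as were Mup21, by -4.24 and -2.44, and C6, by -3.11 and -2.51. Nqo1, which had not passed with alcohol alone, was higher than control with DADS (1.52, adjusted p = 0.00258) and garlic oil (1.29, adjusted p = 0.00633). Its control mean lay under the detection limit, so the sizes of these 2 differences are uncertain. Against alcohol it did not pass with DADS (0.81, adjusted p = 0.141) or garlic oil (0.58, adjusted p = 0.299), so an added effect of the treatments is not shown. Cyp7a1 stayed below control with garlic oil (-3.66, adjusted p = 0.00176) and did not pass with DADS (-1.93, adjusted p = 0.0623). Fgf21 stayed below control with garlic oil (-1.78, adjusted p = 0.0215), and its difference with DADS was -0.08 (95% interval -1.13 to 0.97). These comparisons also cross the chips, so chip and group cannot be told apart. Without control replicate 2 the counts were 888 and 908, and under median scaling the splits were 1743 up and 253 down for DADS and 1004 up and 342 down for garlic oil.

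Of the 300 genes that changed with alcohol, 205 (68.3%) still passed against control with DADS and 227 (75.7%) with garlic oil. The same control arrays served to choose the genes and to test them again. No such share was computed for treatments without effect, so genes that no longer passed cannot be read as restored. The sign of the treatment change was opposite to that of alcohol for 58.3% of them with DADS and 53.3% with garlic oil. In 100 simulations with no treatment effect and the same alcohol arrays on both sides, these shares averaged 70.5% (34.8 to 94.7) and 69.5% (31.7 to 95.2). Splitting the alcohol arrays 2 and 2, so that each side used other arrays, gave averages of 50% and 39% over 6 ways. With DADS, 17 alcohol-changed genes passed in the opposite direction, among them Lpin1, Socs2, Gadd45a, Rdh9, Tef and Cdc20, and 11 passed further along the alcohol direction, among them Cyp2b9, Tsc22d1, Mup21 and C6. Lists drawn independently would share 2.62 and 1.68 genes in the opposite directions and 2.00 and 2.21 in the same ones, where 8 and 9, and 3 and 8, were observed. With garlic oil, 18 passed in the opposite direction, among them Gsta1, Gstm1, Gstm3, Cyp26a1, Fads2 and Cdc20, and 8 passed further along, among them Cyp2b9, C6 and Vcam1. Here independent lists would share 2.16 and 0.95, against 16 and 2 observed, and 1.13 and 1.81, against 4 and 4. Independence is not the value for no effect, because the alcohol arrays stand on both sides. In the simulations 0.02 genes on average (0 to 1) passed in the opposite direction with DADS and 0.80 (0 to 79) with garlic oil. A mean of 0.80 over 100 simulations with a highest count of 79 means that 1 run held nearly all of these genes. The 18 with garlic oil lie under that 1 run, which does not make them usual without an effect. In all, the simulations called only 0.02 genes on average with DADS and 2.76 with garlic oil, so they could hardly return any. Of the genes named here, the calls of Gsta1, Gstm1, Cyp26a1, Cyp2b9, C6 and Vcam1 with garlic oil and of Socs2 with DADS were lost under most alternatives. Without the acinar-rich array of alcohol replicate 1, neither Socs2 (adjusted p = 0.112) nor Gadd45a (adjusted p = 0.0579) passed with DADS.

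Relative to alcohol, 12 genes rose with both treatments and 28 fell with both. Independent lists would share 0.71 and 1.79, which is no measure of a shared effect here, because both comparisons use the same alcohol arrays and cross the same chips, and a chip difference would move the same genes in both. The simulations shared 0 genes in either direction (0 to 0), but they called only 0.02 genes on average with DADS, so they could hardly share any. Cyp17a1, Cyp2b9, Nr1i3, Ppara and Akr1d1 were among the genes that rose with both. The calls of Cyp2b9 and Ppara with garlic oil and of Akr1d1 with DADS were lost under most alternatives. Those that fell with both included E2f1, a cell cycle transcription factor (-1.03 and -0.67), Cdc20, Prc1, Cenpa, a centromere histone (-0.84 and -0.90), G6pc, Bst2, C6 and Sort1, a sorting receptor (-0.93 and -0.75). The calls of Bst2 and C6 with garlic oil were also lost under most alternatives. Across genes, which are not independent replicates, the 2 sets of changes correlated at 0.547, against a mean of 0.509 in the simulations (0.039 to 0.865). The covariance was 0.0575 against 0.0226 (0.00109 to 0.053), a difference of 0.0349. With the alcohol arrays split 2 and 2 the correlation averaged 0.239 (0.148 to 0.311). Neither the simulations nor the split account for the chips.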

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

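The tests on islet, liver, erythroid and macrophage genes below were chosen after the results were seen, and the splits of the arrays were planned before. Of 44 group values (medians of lists and array measures), 2 had 1 array apart from the other 3 by Dixon's test, and chance sets apart about 1 in 20 groups. They were the pancreatic acinar genes on alcohol replicate 1, with a median 9.64 log2 units above the control mean, and the lymphocyte markers on DADS replicate 1 (-0.379 against -0.663 to -0.706 on the other DADS arrays). Among 588 pairs of a named gene and a group, 27 had 1 array apart, near the 5% that chance gives, with DADS replicate 4 most often (6 pairs). The effects of garlic oil and DADS, each against alcohol, differed for 155 genes by the test of the difference.

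Probes outside the reported genes also carried signal. Of 708 probes with no gene name that passed the filter, 28 differed between alcohol and control, 16 higher and 12 lower. On alcohol replicate 1, 48 probes lay at least 4 log2 units above every other array, 38 of them outside the tested genes, while no other array had more than 1 such probe.

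Pancreas genes on alcohol replicate 1 were weighed first. Amy2a5 (15.71), Cela1 (15.64) and Prss2 (15.41) stood there against at most 8.19, 11.06 and 4.9 on the other 15 arrays. An effect of the alcohol diet on liver is argued against by the other 3 alcohol arrays, whose acinar median was -0.16 from controls, and another tissue under the liver label by 19 liver genes of the lists at 8 to 13 log2 units, below the brightest levels, whose median was -0.08 from those arrays, with 0 lower by over 1 log2 unit. Of 4 islet hormone genes Ins2 (10.64), Gcg (6.97) and Sst (6.28) were above all other arrays, Iapp (6.4) was not, and the median excess was 1.74. Pancreatic tissue in that sample is therefore a candidate explanation, and no biological explanation was tested beyond the diet.

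Erythroid genes higher with garlic oil were weighed next. A difference between the 2 chips is argued against by 4 erythroid genes higher than with DADS on the arrays of chip 1 alone, and dependence on 1 garlic oil array by at least 4 genes higher than alcohol whichever array was left out. Position on chip 1 cannot be told apart from treatment. More circulating blood in the samples cannot be told apart from a change in the liver: Alas2 changed by -0.12 while globins rose, but 1 gene does not decide it and blood content was not measured. An effect of garlic oil stays open.

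Macrophage markers lower with DADS were weighed last. A difference between the 2 chips cannot be told apart from an effect. On chip 1 alone the median was 0.67 higher with garlic oil than with DADS, and the list passed by camera with the preset correlation (adjusted p = 4.52e-08) but not with an estimated one (adjusted p = 0.404, unadjusted p = 0.0449). No marker passed there by limma, and 9 of 13 had an unadjusted p under 0.05. Dependence on 1 DADS array is argued against by a median of -0.56 at its closest to 0, without DADS replicate 4, although as few as 2 markers passed by limma with 1 DADS array left out. Without alcohol replicate 1 the median was -0.64 and 1 marker passed. Fewer macrophages in the samples cannot be told apart from lower expression per cell: of 9 markers at 8 log2 units or more 6 passed as lower, Slc40a1, an iron exporter that other cells also make, did not change (adjusted p = 0.999), and cell numbers were not measured. An effect of DADS stays open.

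For each comparison, only 1 of the 35 splits of its 8 arrays into 4 and 4, the real one, gave as many genes by limma. The real and the highest other counts were 300 and 1 for alcohol against control, 238 and 41 for DADS against alcohol, 169 and 13 for garlic oil against alcohol, and 155 and 28 for garlic oil against DADS. They were 1335 and 0 for DADS against control and 1497 and 0 for garlic oil against control. The real split ranked first in all 6, but 1 of 35 is the best rank that so few splits allow. Mixed splits also carry any group difference in their spread, which lowers their counts. The splits therefore do not exclude chance. The real split follows the chips in the 4 comparisons that cross them, so chip and group cannot be told apart there. Within a chip it follows the positions of the arrays.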

How the results depend on the processing

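Removal of alcohol replicate 1 before normalization was added after seeing the data, and the other alternatives were planned. Of 254 alternative counts and shares, 207 stayed within 1.5 times the reported count or 1 SD of the share, 38 counts were lower, 3 were higher and 6 shares moved. None of 4653 values of named genes reversed a call, but calls held under every alternative for only 32 of 63 named genes for alcohol against control, 15 of 47 for DADS against alcohol, 10 of 38 for garlic oil against alcohol and 16 of 39 for garlic oil against DADS. Where no reason is given, the cause was not tested. Median scaling gave 775 genes for DADS against alcohol and 237 for garlic oil against DADS. The authors' values gave 83 genes for garlic oil against alcohol, and no filter gave 136 for DADS against alcohol, with more genes tested. Detection on all 16 arrays left 8 lists for DADS against alcohol. Only the 2 groups, with fewer degrees of freedom, gave 63 genes for DADS against alcohol, 27 for garlic oil against alcohol and 39 for garlic oil against DADS, and the arrays within chip 1 also gave 39. Array weights gave 669 genes for alcohol against control and 96 for garlic oil against alcohol. Without alcohol replicate 1 before normalization DADS against alcohol had 151 genes and garlic oil against alcohol 95. An estimated correlation left 1 list for alcohol against control, 0 for DADS against alcohol (14 at the preset, 6 by fry), 2 for garlic oil against alcohol and 1 for garlic oil against DADS (6 by fry). Alcohol arrays split 2 and 2 gave shares moved back of 50% for DADS and 39% for garlic oil.

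With 1 array left out, which leaves fewer samples, gene counts ranged from 132 (without alcohol replicate 3) to 378 for alcohol against control, from 98 (without alcohol replicate 3) to 233 for DADS against alcohol, from 44 (without garlic oil replicate 4) to 159 for garlic oil against alcohol, and from 72 (without garlic oil replicate 4) to 153 for garlic oil against DADS. Against control they ranged from 888 to 1299 for DADS and from 908 to 1433 for garlic oil, both lowest without control replicate 2. Lists for DADS against alcohol ranged from 9 (without DADS replicate 4) to 17. Shares moved back ranged from 53% to 71.8% for DADS and from 48.5% to 63% for garlic oil, both highest without alcohol replicate 4. Replicate number as a block (replicate block) gave 112 genes for garlic oil against alcohol, but no pairing of the mice by these numbers is stated. Residuals of 24 same-number pairs correlated at 0.008 on average (-0.367 to 0.404). Those of 72 other pairs correlated at -0.003 (-0.334 to 0.431). Averages with so wide a range do not decide whether the numbers pair the mice. Of 12038 probes never detected, limma called between 0 and 3 in any comparison.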

Other observations

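The genes and arrays of this part were chosen after their values were seen, and the cause was not tested. Cholesterol synthesis genes differed within the treated groups: their median lay 1.24 above the control mean on DADS replicate 3 and 0.64 above it on garlic oil replicate 3, and between -0.96 and -0.06 on the other treated arrays. Sqle, squalene epoxidase of that pathway, stood at 10.3 and 9.25 on these 2 arrays and at 7.58 to 8.74 in controls. It lay at 5.32, not detected, on alcohol replicate 2 and at 6.9 to 7.01 on the other alcohol arrays. On the other treated arrays it lay at 5.59 to 7.86. Lcn2, an acute phase gene, reached 14.25 on DADS replicate 3 and lay between 9.7 and 11.57 on the other DADS arrays.

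Among male-biased genes, alcohol replicate 4 lay lower (-1.73) than the other alcohol arrays (-0.85 to -0.33). Hsd3b5, a male-specific steroid enzyme, stood at 13.13 to 13.95 in controls, 11.66 to 12.79 on 3 alcohol arrays and 6.04 on alcohol replicate 4. It was detected on 1 of 4 DADS arrays (8.11) and 3 of 4 garlic oil arrays (8.22 to 11.34). Serpina12, an adipokine-family serpin, stood at 11.58 to 13.03 in controls, 8.21 on alcohol replicate 4 and 8.45 to 10.16 on the treated arrays.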
